A study of Mus musculus with 18 samples.

How the data were processed

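The data were 18 Agilent arrays, each hybridised with Cy5-labelled RNA of sorted macrophages and Cy3-labelled universal mouse reference RNA, per the labels, in the same dye orientation throughout. Dye bias specific to a probe therefore cancels between samples but not in the ratio to the reference. Per the labels' protocols, cells were sorted by flow cytometry on F4/80, Cd11b and CRIg, lysed directly, and their RNA purified on columns. Groups and replicate names were taken from the sample titles. The deposited scanner files give mean and background intensity of each spot in both channels, per the file headers, on a linear scale and not normalised. They also hold a log10 ratio of Cy5 over Cy3 that the scanner software, Agilent Feature Extraction version A.7.5.1, had background-subtracted and dye-normalised, per the file headers. A deposited table of the whole series held log10 ratios that were equal to the scanner's own on every array, limited to the range from -2 to 2, with medians of 0 to 0.0101, so its scale, centring and direction were known. Deposited marks of each spot as above background, saturated or an outlier were used as the software set them, per the file headers. The Kupffer cell arrays had been extracted with another background setting than the others, so the background was taken anew from the raw intensities. The marks of spots as above background were not set anew. They may therefore differ in strictness between Kupffer and other arrays, as may the filter, shares and bounds that rest on them.

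Of 22393 features, 913 positive and 162 negative control spots were left out after background correction and given no weight in normalisation. The 21318 other spots held 20868 probes, 50 of them on more than 1 spot. Background was corrected with normexp and an offset of 50, and each array was normalised by loess in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) and statmod 1.5.0. Outlier spots (19 to 294 per array) were left out, saturated spots (1 to 11 per array in Cy5) were kept, and spots of a probe were averaged. The unit tested was the log2 ratio of Cy5 over Cy3, computed from the deposited intensities. A probe was tested when its Cy5 signal was well above background on all 3 arrays of at least 1 group, which 18997 probes were. The offset and the reference channel both draw folds of dim genes toward 1. Large folds of bright genes can be smaller in the ratio than in Cy5 too. Clec4f had a mean log2 Cy5 signal, after loess and Aquantile, of 15.43 in wild-type Kupffer cells and 5.959 in splenic cells. Its log2 ratio differed by 5.80.

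Probes were named through a RefSeq gene table of assembly GRCm38, used for names alone, 8947 by accession, 368 by a symbol and 364 by a synonym in the file's description, and 44 from the description read by hand. Of 20868 probes, 9723 (46.6%) had 1 symbol, 13 had several and 11132 had none and kept the file's accession. For genes with several probes (129 genes) the brightest was used. This gave 18865 genes, 8942 of them with a symbol. No probe was named Vsig4. Among the genes that the text could name, 2 had more than 1 probe, and neither gave the opposite sign in a comparison that was called.

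One linear model with 6 group means (12 residual degrees of freedom) was fitted to all 18 arrays with lmFit and eBayes, with a prior of 3.744 degrees of freedom, and p-values were adjusted by Benjamini and Hochberg within each of 6 comparisons, with 0.05 as the threshold. An F test covered any difference among the 6 groups. The difference between the CRIg effect in the peritoneum and in the liver was tested as an interaction. Gene lists (28, for macrophage populations, other cell types the gates could hold, and pathways) were tested with camera at its preset correlation of 0.01, adjusted over the 28 lists of a comparison, with an estimated correlation and fry beside it. Under a random block the lists were tested with cameraPR on the moderated t values, which without a block gave the call of camera for every list but 1, the Fc receptor genes of Kupffer wt against peritoneal. The numbers of lists called by camera were 3 for the knockout, 1 for the peritoneal gates, 15 for the splenic gates, 11 for each comparison with Kupffer wt cells and 13 for peritoneal against splenic. With an estimated correlation they were 0, 0, 7, 5 (against peritoneal), 7 (against splenic) and 1. Fry, which asks whether a list's genes move one way on balance, called 0, 0, 21, 19, 22 and 21 lists in the same order, and its mixed test, which asks whether they change either way, 2, 0, 26, 26, 28 and 26. Several lists share genes, such as Slc40a1, Hmox1 and Spic among the Kupffer cell and red pulp lists, and erythroid and B cell genes were listed as other cells that a splenic gate could hold. Samples, comparisons, lists, the rule for named genes and the other settings to try were fixed before the data were examined.

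Genes named in the text were Vsig4, Adgre1 and Itgam in every comparison, and among genes with an adjusted p under 0.05, ranges that did not overlap and a gene symbol, the 10 largest rises and 10 largest falls within a tissue, or the 8 and 8 largest between tissues. For each list they were up to 4 passing members with the largest change on each side, or up to 2 as values where none passed, and in the knockout any passing gene that flanks Vsig4. Other genes are said to have been chosen after their values were seen. This holds for AK041014 in every comparison. A gene that this rule would have named is not reported here. A probe that was above background on no array of a group has only a bound there. It was computed as the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest Cy5 signal well above background and the probe's own, after loess and Aquantile, and it is open to dye bias.

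The letter pairs in the titles of the peritoneal and splenic arrays were checked as pairs. The deviations of same-letter arrays from their group means correlated across genes. The r lay between 0.277 and 0.744 in the peritoneum and between 0.260 and 0.455 in the spleen, each above 0.1. Of 6 arrays each, 4 in the peritoneum and 6 in the spleen correlated best with the array of their own letters. These arrays were taken as paired in the alternative fits with the letter pair as a block. The main fit held no block, so its SE and p-values treat them as independent. The labels used here do not say what the letters mark. The day on which the scanner software extracted an array's signals, given per the file headers, was used as a batch. It need not be the day of hybridisation or scanning.

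Background correction, loess, the limma fit and camera were tested on simulated data with known changes in a seeded set of genes and in 1 list before use. The simulated noise was drawn independently for each probe and array. The counts of false calls below therefore do not cover correlation between genes, within letter pairs or within days. Genes changed 4-fold were all recovered in every comparison. Of those changed 2-fold, between 97.0% (Kupffer wt against splenic) and 100% (Kupffer ko against wt) of 18865 genes' changed members were recovered, and of those changed 1.5-fold between 73.1% (splenic gates) and 94.0% (Kupffer wt against splenic). False calls numbered 7 in the knockout comparison, 14 in each comparison of gates, 9 for Kupffer wt against peritoneal and 10 in each of the other 2. True 2-fold changes came out with a median log2 of 0.70 to 0.77, so the folds given here are compressed. The list whose genes were all shifted, the iron and heme genes, was called by camera in each comparison. Of the 28 lists, 1 other was called in 5 comparisons and 2 others for peritoneal against splenic. These were the red pulp list, with 6 genes in common with the shifted list, and there also the Kupffer cell list, with 2 in common.

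Alternatives covered the scanner's own log ratios and the deposited table, an offset of 16, median centring without loess, Aquantile or scale normalisation between arrays, the Cy5 channel alone, no filter and a stricter filter (both channels above background on 9 of 18 arrays), the mean of all probes, the letter pair as a block, the day as a block, array weights, an intensity trend with a robust prior, fits of the compared arrays alone, single gates, a 2-fold threshold and leaving out each array in turn.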

Results

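Gene expression was measured in macrophages sorted from the liver, the peritoneal cavity and the spleen of mice, on 18 arrays that compared each sample, in the Cy5 channel, with a common reference RNA, in the Cy3 channel. The sorts used F4/80 (encoded by Adgre1), Cd11b (encoded by Itgam) and CRIg, a complement receptor of tissue-resident macrophages that is encoded by Vsig4. The 6 groups held 3 arrays each. They were Kupffer cells, the resident macrophages of the liver, from wild-type (wt) and CRIg-knockout (ko) mice, peritoneal macrophages with high CRIg or without CRIg, and CRIg-negative splenic macrophages with intermediate F4/80 and no Cd11b or with low F4/80 and low Cd11b. Per the labels each sample was a pool of 20 mice, so the spread between arrays is that between pools and hybridisations. Sample signal was above background for between 74.8% and 92.5% of spots per array. The group means of that share ran from 80.6% in ko Kupffer cells and 81.4% in the F4/80-low splenic cells to 92.0% in CRIg-high peritoneal cells, and 3 arrays per group limit the precision. Arrays of the same group correlated across genes with Pearson's r between 0.934 and 0.988, and arrays of different tissues with r between 0.655 and 0.864. Changes are given as log2 ± SE from 1 limma fit over all 18 arrays, with n = 3 arrays per group, or fewer where outlier spots were left out, as given for each such gene, and counts are genes with an adjusted p under 0.05.

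Across the 6 populations, 8151 of 18858 genes (43.2%) differed in at least 1 group by the F test of the fit, and 9720 had an unadjusted p under 0.05. Comparisons between tissues called 5426 to 6310 genes and the splenic gates 3034, against 24 for the knockout and 1 for the peritoneal gates.

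**Figure D1:**
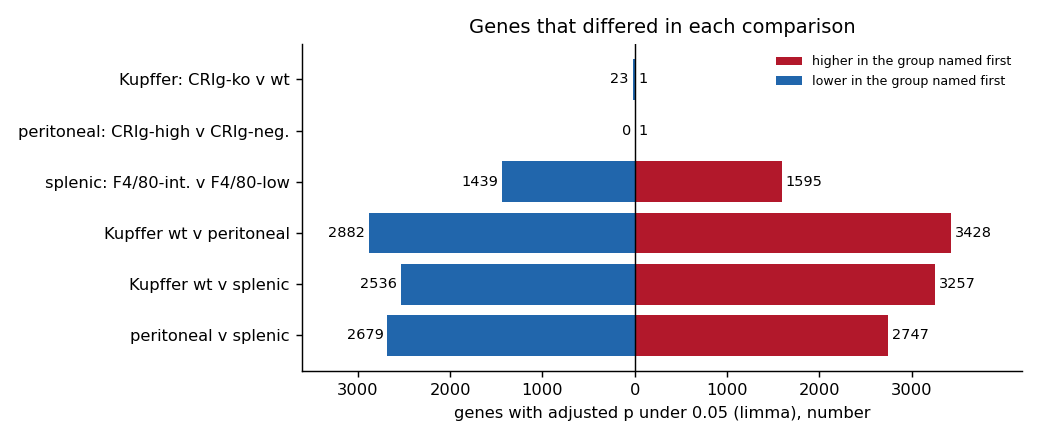
Number of genes (x axis) with an adjusted p under 0.05 in each of the 6 comparisons (y axis), with red bars for genes higher and blue bars for genes lower in the group named first. Between 5426 and 6310 genes differed between tissues, 24 between ko and wt Kupffer cells and 1 between the peritoneal gates.

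The first comparison asked what loss of CRIg changed in Kupffer cells. No probe carried the name Vsig4, so no level could be given for the targeted gene by name. A single probe, named in the files only by the accession AK041014, followed the genotype with the largest change of the comparison. It fell by 4.21 ± 0.080 on the log2 scale in ko cells (18.5-fold, adjusted p = 6.85e-14), from a mean log2 ratio to the reference of 4.47 ± 0.045 (SD, n = 3) in wt cells to 0.27 ± 0.081 (SD, n = 3) in ko cells. This probe was chosen after its values were seen. The sort markers were not called, with Adgre1 at -0.01 ± 0.21 (adjusted p = 0.995) and Itgam at 0.17 ± 0.092 (adjusted p = 0.490).

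**Figure D2:**
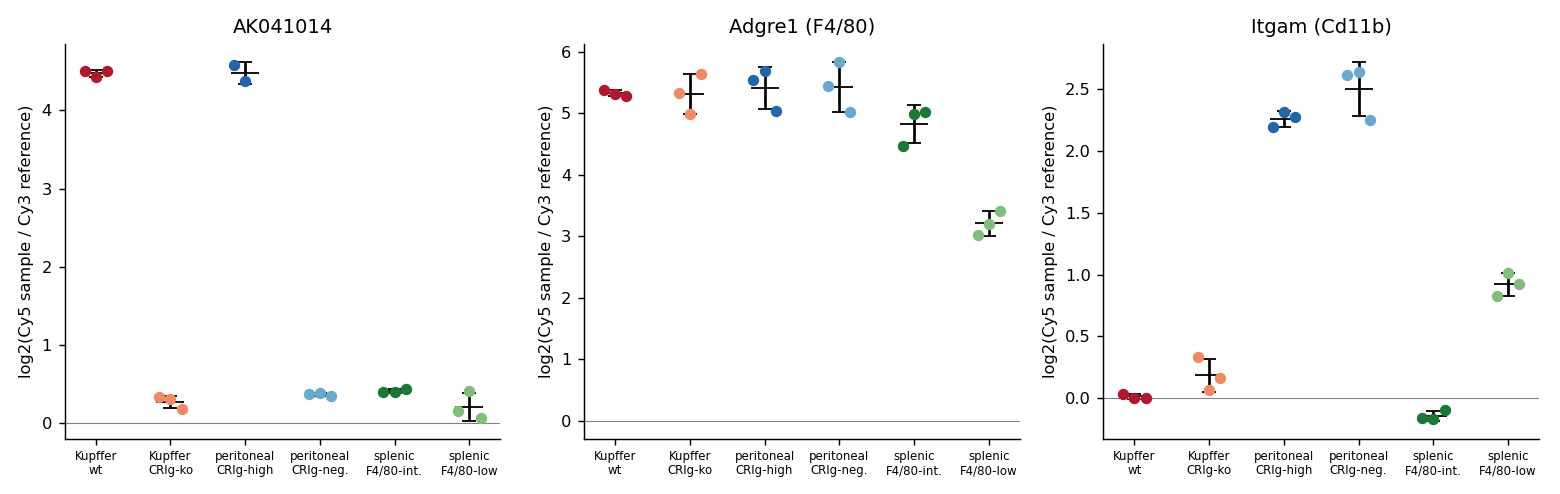
Log2 ratio of sample to reference (y axes) for AK041014, Adgre1 and Itgam on each array, by group (x axes). Points are arrays and black lines the mean ± SD of 3 arrays, except for AK041014 in CRIg-high peritoneal cells, where the third spot was left out; AK041014 is high only on the wt Kupffer and CRIg-high peritoneal arrays.

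Beyond this probe, the called changes in the ko Kupffer cells were small in the log ratios used here. In all, 23 genes were lower and 1 was higher, and no other called gene reached 2-fold. With the scanner's own log ratios Nek3, Olfr1132 and Rb1cc1 stood at -1.51, -1.16 and -1.01, none of them called (adjusted p = 0.140, 0.372 and 0.140), and Kcns2, chosen after its values were seen, was called at -1.47 (adjusted p = 0.0478). Of the 8 with a gene symbol, Olfr727 rose by 0.28 ± 0.052 and 7 fell. Nek3, a kinase gene, fell by 0.58 ± 0.083 (adjusted p = 0.0214) and Rb1cc1, which encodes an autophagy initiation factor, fell by 0.48 ± 0.086. Ptprn2 fell by 0.46 ± 0.085 and Tmem47 by 0.33 ± 0.058. The others were the receptor genes Olfr1132 (-0.40 ± 0.056), Olfr1261 (-0.38 ± 0.068) and Vmn1r70 (-0.34 ± 0.061). Signal was above background on only 1 of 3 ko and 2 of 3 wt arrays for Nek3, on 2 of 3 arrays of each group for Olfr1132, on 2 of 3 wt arrays for Olfr1261 and on 2 of 3 ko arrays for Vmn1r70. For most genes that fell, mean log2 Cy5 signal after loess and Aquantile, ko against wt, changed less than the ratio. It was 6.467 against 6.557 for Rb1cc1, 6.873 against 6.896 for Ptprn2 and 6.398 against 6.44 for Tmem47. Olfr1132 was at 6.134 against 6.232, Vmn1r70 at 6.291 against 6.367 and Nek3 at 6.089 against 6.394. Olfr1261 was higher in ko cells (6.613 against 6.2). Part of these falls thus lay in the Cy3 reference channel.

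None of the gene lists held a gene that passed in this comparison, although Ccl2 did with the day as a block, where ko array 2 alone stood for the ko cells (1.02, adjusted p = 0.0124), Eda without wt array 1 (adjusted p = 0.0421) and Oasl2 without wt array 3 (adjusted p = 0.0320). None of 17 Kupffer cell genes passed (camera adjusted p = 0.932, or 1.68e-05 and higher with scaling between arrays, with Spic at 0.39 ± 0.18 and Id3 at 0.31 ± 0.13), nor any of 10 genes that flank Vsig4 on chromosome X (camera adjusted p = 0.903, with Eda at -0.21 ± 0.053 and Efnb1 at -0.18 ± 0.12). Adjusted over the list alone, 1 flanking gene was lower. As sets, 3 lists shifted upward in ko cells with the preset correlation, and none did with an estimated correlation (adjusted p = 0.948 each). They were the 13 interferon-stimulated genes (adjusted p = 0.00821, with Irf7 at 0.44 ± 0.15 and Oasl2 at 0.37 ± 0.097), the 19 large peritoneal macrophage genes (adjusted p = 0.010, with Prg4 at 1.24 ± 0.38 and Fn1 at 0.75 ± 0.27) and the 21 inflammatory cytokine and chemokine genes (adjusted p = 0.0425, with Ccl2 at 0.46 ± 0.27 and Ccl3 at 0.46 ± 0.50). Ccl2 rested on 2 ko arrays and Spic on 2 wt arrays. Adjusted over the list alone, 3 interferon-stimulated, 3 large peritoneal macrophage and 0 inflammatory genes were higher. Without ko array 1 all 3 were lost (adjusted p = 0.0887, 0.288 and 0.818), the large peritoneal list also without wt array 1 (0.0741), and the inflammatory list without wt array 2 (0.0794) or 3 (0.513). The inflammatory call was also lost with the scanner's own log ratios (0.135), an offset of 16 (0.0520) and no signal filter (0.110), the inflammatory and large peritoneal calls with the stricter filter (0.0543 each), and all 3 with fry (0.547 each).

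The count of 24 genes (2254 at an unadjusted p under 0.05; over all genes 16.1% had ranges that did not overlap, which chance gives in 10% for 3 arrays against 3) rested on single arrays. It was 172 without wt array 1, 55 without wt array 3, 2 without ko array 2 and 1 without wt array 2, ko array 1 or ko array 3. The signals of the ko arrays were extracted by the software on 3 days, and those of the wt arrays on the day of ko array 2. Both the day as a block and a fit within that day leave ko array 2 alone for the ko cells, assumed to vary like the other groups. They called 722 genes, 20 of them among the 24, and 689, 19 of them among the 24, and so do not test the 3 ko arrays. AK041014 stayed at -4.17 in both, while the camera adjusted p of the large peritoneal, interferon and inflammatory lists rose to 0.972, 0.972 and 0.996 with the block and to 0.994 each within the day. The count was 2 with the scanner's own log ratios, 2 with scaling between arrays and 1 with the arrays only centred on their medians, and AK041014 was called in each. In the Cy5 channel alone Olfr1261, Ptprn2 and Tmem47 turned, to 0.55, 0.038 and 0.0037.

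The second comparison set CRIg-high against CRIg-negative peritoneal macrophages, which asks what else separates cells sorted on CRIg. AK041014 was the only gene called of 18860 tested (403 at an unadjusted p under 0.05 in limma). It was 4.12 ± 0.090 higher in CRIg-high cells (17.3-fold, adjusted p = 4.84e-13), with a mean log2 ratio of 4.48 ± 0.14 (SD, n = 2) against 0.36 ± 0.020 (SD, n = 3), since its spot was left out on 1 CRIg-high array. Over all genes 9.58% had ranges that did not overlap, which chance gives in 10%. Adgre1 differed by -0.01 ± 0.21 and Itgam by -0.24 ± 0.092 (adjusted p = 1.00 for each). The change of AK041014 in peritoneal cells differed from that between wt and ko Kupffer cells by -0.09 ± 0.12 (adjusted p = 0.995). No gene of 18858 differed between these 2 changes in limma, with 947 at an unadjusted p under 0.05.

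Cell cycle genes were the 1 list that moved between the peritoneal gates. They were lower in CRIg-high cells as a set (camera adjusted p = 2.56e-09; adjusted p = 0.424 with an estimated correlation). Their median log2 change was -0.18, and none of 21 measured members passed over all genes tested or adjusted over the list alone. The helicase genes Mcm4 and Mcm6 stood at -0.35 ± 0.16 and -0.34 ± 0.14. This call was lost with arrays only centred on their medians (adjusted p = 0.0821), with scaling between arrays (adjusted p = 0.216) and with fry (adjusted p = 0.980). The 19 large peritoneal macrophage genes gave an adjusted p of 0.737, with Arg1, which encodes arginase, at 0.57 ± 0.18 and Prg4 at 0.39 ± 0.66 (1 array per gate, assumed to vary like the other groups), and adjusted over the list alone 1 was higher and 1 lower. The 9 small peritoneal macrophage genes gave an adjusted p of 0.0934, with Retnla at -0.64 ± 0.26 and Ccr2 at -0.40 ± 0.15, and 0.0410 or 0.0446 without the CRIg-high or CRIg-negative MN array. The 8 mesothelial genes gave an adjusted p of 0.969, with Msln at -0.15 ± 0.18 and Cldn15 at 0.15 ± 0.078. Scaling between arrays gave these 3 lists adjusted p of 7.28e-15 (lower), 0.000541 (lower) and 0.00855 (higher). With the letter pair as a block, 3 genes were called. They were AK041014 at 4.10, Arg1 at 0.57 (adjusted p = 0.0489) and a gene named only BC018464 at -0.59 (adjusted p = 0.0324), the last chosen after its values were seen.

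The third comparison set the F4/80-intermediate against the F4/80-low splenic gate. The F4/80-intermediate cells were higher in genes of red pulp macrophages, which recycle iron from aged red cells. Vcam1, an adhesion molecule, was 5.93 ± 0.21 higher (61.1-fold, adjusted p = 3.98e-11). Slc40a1, the iron exporter ferroportin, rose by 4.86 ± 0.16 and Hmox1, which degrades heme, by 4.42 ± 0.19. Spic, the transcription factor of red pulp macrophages, rose by 3.86 ± 0.16. All 12 measured red pulp macrophage genes were higher (camera adjusted p = 2.93e-20). Of 18 iron and heme genes 8 rose and 1 fell (adjusted p = 1.42e-05), among them Cd163, the receptor for hemoglobin bound to haptoglobin (3.24 ± 0.24), and Hebp1, a heme-binding protein (3.13 ± 0.19, on 2 F4/80-intermediate arrays). The 1 that fell was Hp, haptoglobin itself (-3.65 ± 0.21), with signal above background on 2 of 3 F4/80-intermediate arrays. Counts adjusted over the list alone were the same for both lists.

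The other large rises in F4/80-intermediate cells were Cd5l, a secreted scavenger protein (4.89 ± 0.26), the mannose receptor Mrc1 (4.55 ± 0.14), Pld3 (4.01 ± 0.11), the cyclooxygenase gene Ptgs1 (3.99 ± 0.16), the lipid phosphatase gene Plpp3 (3.93 ± 0.21) and the tetraspanin gene Tspan4 (3.88 ± 0.20). Of 17 Kupffer cell genes 10 rose and 2 fell (camera adjusted p = 6.97e-09), and adjusted over the list alone 11 rose and 2 fell. Of 19 scavenger and efferocytosis receptors 9 rose and 3 fell (adjusted p = 0.00439; adjusted p = 0.196 with an estimated correlation, and 0.0546 with the scanner's own log ratios), among them Mertk (3.68 ± 0.19) and Marco (2.56 ± 0.25). Of 19 complement genes 9 rose and 2 fell (adjusted p = 0.0148; adjusted p = 0.196 with an estimated correlation, 0.0785 with scaling between arrays and 0.0725 on the splenic arrays alone). C1qb rose by 3.1 ± 0.24, C2 by 2.27 ± 0.11 and Cfp, which encodes properdin, by 2.21 ± 0.24, and adjusted over the list alone 9 rose and 4 fell. The sort markers moved with the gates, Adgre1 by 1.62 ± 0.21 (adjusted p = 3.66e-05) and Itgam by -1.06 ± 0.092 (adjusted p = 2.94e-07).

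Genes higher in the F4/80-low cells were those of monocytes, neutrophils and small peritoneal macrophages. Lyz2, lysozyme of myeloid cells, differed by -4.19 ± 0.26 (18.2-fold, adjusted p = 6.21e-09). Ccr2, the chemokine receptor of inflammatory monocytes, differed by -3.32 ± 0.15, with signal above background on 2 of 3 F4/80-intermediate arrays, and F13a1, a coagulation factor gene of monocytes, by -2.99 ± 0.29. Of 13 monocyte genes 8 were lower (camera adjusted p = 1.51e-10), including Chil3 (-2.56 ± 0.29), and adjusted over the list alone 10 were lower and 1 higher. Of 9 small peritoneal macrophage genes 6 were lower (adjusted p = 3.82e-08), including Itgax (-1.86 ± 0.12), Clec10a (-1.80 ± 0.18) and Retnla (-2.95 ± 0.26), as adjusted over the list alone. Of 12 neutrophil genes 7 were lower (adjusted p = 1.24e-07), as adjusted over the list alone. S100a9 fell by 2.72 ± 0.17 and Mmp9 by 1.38 ± 0.13, and S100a8, not well above background in F4/80-intermediate cells, was at least 1.80-fold lower there. The other large falls were Cbfa2t3 (-3.59 ± 0.28), Emp3 (-3.19 ± 0.18), Mefv, which encodes pyrin (-3.04 ± 0.13), the inhibitory Fc receptor gene Fcgr2b (-2.99 ± 0.32) and Lsp1 (-2.98 ± 0.19).

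**Figure D3:**
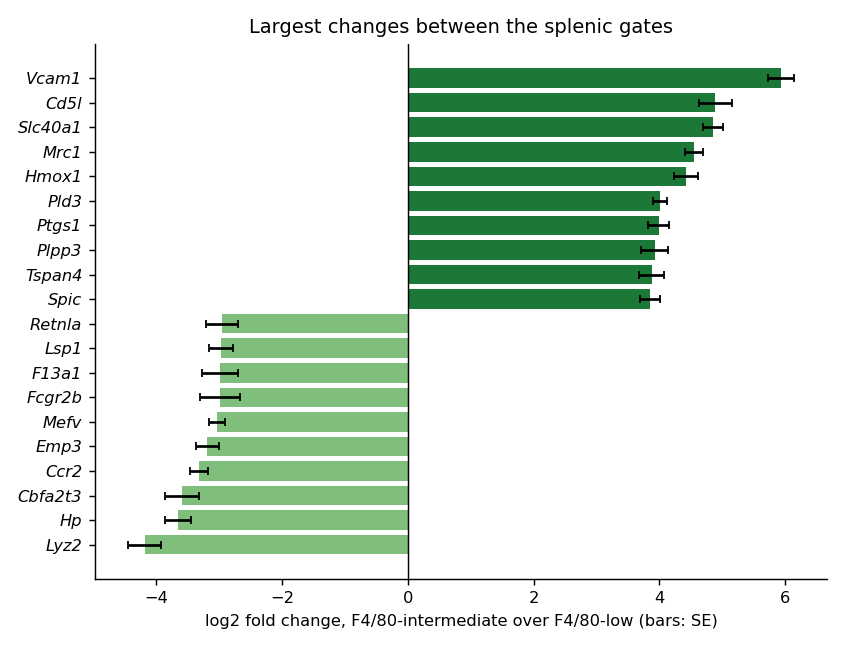
Log2 fold change (x axis) between the F4/80-intermediate and F4/80-low splenic gates for the 10 largest rises and the 10 largest falls (y axis), with bars for the estimate and error bars for the SE (n = 3 arrays per gate). The rises reach 5.93 for Vcam1 and the falls -4.19 for Lyz2.

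Antigen presentation, dendritic cell, coagulation, large peritoneal macrophage and immediate early genes were also lower in the F4/80-intermediate gate as sets, but none of these 5 calls held with an estimated correlation. Of 12 MHC class II genes 6 were lower and 1 higher (adjusted p = 0.00144; adjusted p = 0.226 with an estimated correlation), with H2-Oa at -2.21 ± 0.15 (2 F4/80-low arrays), H2-Eb1 at -1.66 ± 0.32 and the costimulatory gene Cd86 at 1.29 ± 0.26, and adjusted over the list alone 7 were lower. Of 11 dendritic cell genes 6 were lower and 2 higher (adjusted p = 0.00860; adjusted p = 0.265 with an estimated correlation), with Dpp4 at -1.84 ± 0.20 and Cadm1 at 2.49 ± 0.16, and adjusted over the list alone 7 were lower. Of 21 coagulation genes 7 were lower and 1 higher (adjusted p = 0.00255; adjusted p = 0.103 with an estimated correlation), with F10 at -1.99 ± 0.18 and Thbd at -1.75 ± 0.25, and adjusted over the list alone 8 were lower. Of 19 large peritoneal macrophage genes 7 were lower (adjusted p = 0.000103; adjusted p = 0.182 with an estimated correlation), F10 among them, and 9 adjusted over the list alone. Of 21 immediate early and stress genes 7 were lower (adjusted p = 1.87e-05; adjusted p = 0.286 with an estimated correlation), with Klf4 at -2.58 ± 0.61 and Nr4a1 at -2.33 ± 0.32, as adjusted over the list alone.

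Genes of red cell precursors and B cells moved with the red pulp genes. Of 13 erythroid genes 9 rose in F4/80-intermediate cells (camera adjusted p = 6.63e-09), including Car2 (1.78 ± 0.18), Slc4a1, the red cell anion exchanger (1.69 ± 0.18), and Alas2, the first enzyme of heme synthesis in red cell precursors (1.60 ± 0.27), and adjusted over the list alone 11 rose and 1 fell. Of 13 B cell genes 8 rose (adjusted p = 3.22e-07; adjusted p = 0.0507 with an estimated correlation), including Cd79b (1.5 ± 0.19), Ly6d (1.40 ± 0.18) and Pou2af1 (1.25 ± 0.20), and 10 adjusted over the list alone. AK041014 did not differ between these CRIg-negative gates by the test (0.20 ± 0.080, adjusted p = 0.119), but did without the F4/80-low ST array (0.30, adjusted p = 0.00901).

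In all 1595 genes were higher and 1439 lower in F4/80-intermediate cells, 16.1% of 18865, 667 of them by at least 2-fold. Over all genes 28.7% had ranges that did not overlap, which chance gives in 10% for 3 arrays against 3. Of the 3034 called, 2909 were among them. The signals of each gate's arrays were extracted by the software on 2 days. With the day as a block 3243 genes were called, and 1964 within the day of the OP and ST arrays. Of these 1964, 1911 were among the 3034. The day of the WX arrays holds only 1 array per gate and so gives no test of its own. No list named here lost its call under the block or within the day of the OP and ST arrays. The count was 1654 with arrays only centred on their medians, and Cd163 was at 0.90 (adjusted p = 0.437) with the scanner's own log ratios. Single-gene calls were also lost for Alas2 with those ratios (adjusted p = 0.0510), for Klf4 within the day of the WX arrays (0.0585) and on the splenic arrays alone (0.0855), and for Cd86 on the splenic arrays alone (0.0557).

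The fourth comparison set wt Kupffer cells against the mean of both peritoneal groups. Kupffer cells were higher in Kupffer cell and red pulp macrophage genes, and peritoneal cells in large peritoneal macrophage genes. Slc40a1 was 6.04 ± 0.14 higher in Kupffer cells (65.7-fold, adjusted p = 3.76e-14). Clec4f, a lectin of Kupffer cells, was 5.84 ± 0.095 higher, with signal above background on 1 of 6 peritoneal arrays, and Clec1b, the receptor for podoplanin, 5.02 ± 0.14. Itgb5 rose by 5.43 ± 0.13, the prostaglandin-degrading enzyme gene Hpgd by 4.65 ± 0.13, Gadd45g by 4.41 ± 0.31, Vcam1 by 4.33 ± 0.18 and Adamdec1 by 4.16 ± 0.17. Of 17 Kupffer cell genes 13 were higher (camera adjusted p = 6.97e-15) and none lower, as adjusted over the list alone. Of 12 red pulp genes 9 were higher and 1 lower (adjusted p = 3.51e-07), with Spic at 3.53 ± 0.16 (2 wt arrays), Hmox1 at 3.01 ± 0.16 and the transferrin gene Trf at -1.61 ± 0.14, and adjusted over the list alone 10 were higher.

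Peritoneal cells carried the large peritoneal macrophage genes. Of 19 of these, 18 were lower in Kupffer cells (camera adjusted p = 1.08e-24), as adjusted over the list alone. Saa3, a serum amyloid gene, differed by -6.66 ± 0.17 (101-fold), Prg4, the lubricant lubricin, by -6.43 ± 0.43 (2 of 6 peritoneal arrays), the fibronectin gene Fn1 by -5.77 ± 0.23 and the lipoxygenase gene Alox15 by -4.83 ± 0.18. Saa3 and Prg4 were above background on 1 of 3 Kupffer arrays. Serpinb2, a plasminogen activator inhibitor gene, was not well above background in Kupffer cells. It was 53.9-fold lower there in the fit (adjusted p = 1.17e-11), and at least 68.5-fold lower by its Cy5 signal after loess and Aquantile. Cd9 was at -5.21 ± 0.17, Clec4d at -4.76 ± 0.20 and the chemokine gene Pf4 at -4.73 ± 0.20 (5 of 6 peritoneal arrays). Of 21 coagulation genes 9 were lower and 2 higher (adjusted p = 0.00663; adjusted p = 0.164 with an estimated correlation, 0.0707 with the Cy5 channel alone and 0.133 with the stricter filter), with F10 at -4.14 ± 0.16, F13a1 at -3.71 ± 0.25 and Procr at 2.06 ± 0.15, and adjusted over the list alone 3 were higher. Of 12 eosinophil and mast cell genes 7 were lower (adjusted p = 0.00277; adjusted p = 0.0667 with an estimated correlation, and 0.0707 with the Cy5 channel alone), among them Hdc, which makes histamine (-3.01 ± 0.11), and the mast cell chymase gene Cma1 (-1.91 ± 0.11), as adjusted over the list alone. Itgam fell by 2.37 ± 0.080 (adjusted p = 1.35e-12). Adgre1 differed by -0.10 ± 0.19 (adjusted p = 0.727), but by -1.10 with scaling between arrays (adjusted p = 0.0247).

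Interferon-stimulated genes were higher in Kupffer cells, 12 of 13 (camera adjusted p = 1.02e-09), as adjusted over the list alone, including Ifit3 (2.51 ± 0.13), Cxcl10 (2.10 ± 0.20) and Irf7 (1.69 ± 0.13). Of 12 MHC class II genes 7 were higher and 2 lower (adjusted p = 0.00663; adjusted p = 0.365 with an estimated correlation, and 0.290 with scaling between arrays), as adjusted over the list alone, with H2-Ab1 at 3.34 ± 0.32, H2-Eb1 at 2.66 ± 0.27, Cd74 at 2.30 ± 0.28 and H2-Oa at -0.51 ± 0.12. Of 21 inflammatory genes 9 were higher and 3 lower (adjusted p = 0.0284; adjusted p = 0.365 with an estimated correlation, 0.0738 without wt array 1, 0.0800 with scaling between arrays and 0.0849 with the Cy5 channel alone), with Ccl4 at 2.43 ± 0.44, Ccl3 at 1.95 ± 0.43 and Ccl9 at -2.94 ± 0.092, and adjusted over the list alone 11 were higher. Of 21 immediate early and stress genes 10 were higher (adjusted p = 0.0281; adjusted p = 0.603 with an estimated correlation, 0.0661 without wt array 2 and 0.0543 with fry), with Jun at 2.27 ± 0.56, as adjusted over the list alone. Of 17 Fc receptor and phagocytosis genes 9 were higher and 3 lower (adjusted p = 0.0485; adjusted p = 0.365 with an estimated correlation), with Fcgr1 at 1.71 ± 0.20 (5 of 6 peritoneal arrays) and Fcgr2b at -3.56 ± 0.28, and adjusted over the list alone 11 were higher and 4 lower. The Fc receptor call was lost without the CRIg-high UV array (adjusted p = 0.0661), the CRIg-negative UV array (0.0642), wt array 1 (0.0516) or wt array 2 (0.0607), with scaling between arrays (0.907), the scanner's own log ratios (0.114), an offset of 16 (0.0831), arrays only centred on their medians (0.0601), the Cy5 channel alone (0.0556), the stricter filter (0.100), the compared arrays alone (0.0703) and the letter pair as a random block (0.0561).

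Hepatocyte genes moved with the Kupffer genes, 14 of 16 being higher in Kupffer cells (camera adjusted p = 1.17e-08) and 15 adjusted over the list alone. The urinary protein gene Mup1 was 3.26 ± 0.16 higher, Fabp1 1.72 ± 0.14, the fibrinogen gene Fgb 1.18 ± 0.11 and the albumin gene Alb 1.05 ± 0.13. Of 14 liver endothelial genes 8 were higher and 3 lower (adjusted p = 0.102), as adjusted over the list alone, with Stab2 at 1.57 ± 0.090 and Gpr182 at 1.5 ± 0.24. Fabp1 and Ecm1 rested on 5 of 6 peritoneal arrays. Of 12 stellate cell and fibroblast genes 3 were higher and 1, Ecm1 at -4.13 ± 0.21, lower (adjusted p = 0.824), as adjusted over the list alone, and the list's median change, 0.047, and mean, -0.23, differ in sign. Of 11 platelet genes 2 were higher and 2 lower (adjusted p = 0.869), as adjusted over the list alone, with Clec1b and Pf4 the largest on each side. Of 19 complement genes 4 were higher and 9 lower (adjusted p = 0.0768, and 0.0476 without wt array 3 or 0.00160 with scaling between arrays), with C2 at 2.76 ± 0.091, C4b at -2.02 ± 0.19 and C3 at -1.91 ± 0.16, and adjusted over the list alone 10 were lower.

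AK041014 was 2.05 ± 0.072 higher in wt Kupffer cells than in the mean of both peritoneal groups (5 of 6 arrays, adjusted p = 9.10e-12), but level with the CRIg-high group alone (-0.0040, adjusted p = 0.981). In all 3428 genes were higher and 2882 lower in Kupffer cells, 33.5% of 18859, and 816 of these differed by at least 2-fold. Of the 6310, 5386 had ranges that did not overlap. The software extracted all wt Kupffer arrays on 1 day and all peritoneal arrays on another, so batch and group cannot be told apart gene by gene. The count was 3933 with arrays only centred on their medians.

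The fifth comparison set wt Kupffer cells against the mean of both splenic gates. Clec4f was 5.80 ± 0.095 higher in Kupffer cells (55.6-fold, adjusted p = 7.45e-16), with signal above background on 1 of 6 splenic arrays, the lipid-binding protein gene Fabp7 4.67 ± 0.15 and the folate receptor gene Folr2 4.12 ± 0.17. The apolipoprotein gene Apoc1 rose by 4.0 ± 0.18, Gadd45g by 3.60 ± 0.31, Clec1b by 3.56 ± 0.14, Ctla2a by 3.56 ± 0.16 and C4b by 3.22 ± 0.19, and Ctla2a was above background on 4 of 6 splenic arrays. Of 17 Kupffer cell genes 14 were higher and 1, Spic (-0.82 ± 0.16, on 2 wt arrays), lower (camera adjusted p = 2.77e-14), as adjusted over the list alone. Of 19 scavenger and efferocytosis receptors 13 were higher (adjusted p = 2.51e-07), including Marco (2.82 ± 0.22), the endothelial and macrophage receptor gene Stab1 (2.10 ± 0.18) and Msr1 (1.89 ± 0.14), as adjusted over the list alone. Of 19 complement genes 11 were higher and 5 lower (adjusted p = 0.0146; adjusted p = 0.201 with an estimated correlation, 0.470 against the F4/80-intermediate gate and 0.773 with scaling between arrays), as adjusted over the list alone, with C2 at 1.59 ± 0.091 and C3 at -1.71 ± 0.16. Of 13 interferon-stimulated genes 7 were higher (adjusted p = 0.00694; adjusted p = 0.287 with an estimated correlation), with Irf7 at 1.09 ± 0.13 and Ifit2 at 0.92 ± 0.10, as adjusted over the list alone. The interferon call was lost without both splenic OP arrays (adjusted p = 0.0655), against the F4/80-low gate (0.0552), with the Cy5 channel alone (0.258) and with scaling between arrays (0.476).

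Splenic cells were higher in genes of lymphocytes and red cell precursors. The cytokine gene Ltb differed by -4.33 ± 0.17 (20.2-fold), the stress gene Ddit4 by -4.00 ± 0.30 (4 of 6 splenic arrays), Tspan13 by -3.92 ± 0.21, Napsa by -3.42 ± 0.091, Itgax, which encodes Cd11c, by -3.22 ± 0.11, Ly6d by -2.92 ± 0.16 and Nup210 by -2.79 ± 0.16. Of 13 B cell genes 9 were lower in Kupffer cells (camera adjusted p = 1.37e-08), including Cd79b (-1.92 ± 0.17) and Pou2af1 (-1.85 ± 0.17), and 10 adjusted over the list alone. Of 20 T and NK cell genes 8 were lower (adjusted p = 0.00190), including Cd2 (-0.98 ± 0.10), and adjusted over the list alone 8 were lower and 1 higher. The T and NK cell call was lost with the Cy5 channel alone (adjusted p = 0.0729). Of 13 erythroid genes 10 were lower (adjusted p = 1.91e-07), including Alas2 (-1.98 ± 0.24) and Slc4a1 (-1.45 ± 0.16), and 12 adjusted over the list alone. Of 11 dendritic cell genes 6 were lower and 1 higher (adjusted p = 0.00581; adjusted p = 0.282 with an estimated correlation), with Dpp4 at -1.53 ± 0.18, as adjusted over the list alone. Hepatocyte genes were again higher in Kupffer cells, 14 of 16 (adjusted p = 6.41e-10) and 15 adjusted over the list alone, with Mup1 at 3.11 ± 0.16, Fabp1 at 1.59 ± 0.14 and Alb at 1.11 ± 0.13.

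Several differences from the spleen depended on the gate. Of 12 red pulp genes 6 were higher and 2 lower in Kupffer cells (camera adjusted p = 0.105), as adjusted over the list alone, with Slc40a1 at 2.22 ± 0.14, Siglec1 at 1.66 ± 0.13 and Vcam1 at -0.95 ± 0.18. The list was lower against the F4/80-intermediate gate (adjusted p = 0.000486) and higher against the F4/80-low gate (adjusted p = 1.76e-10). Slc40a1 was at -0.21 against the F4/80-intermediate gate and 0.65 (adjusted p = 0.192) with scaling between arrays, and Vcam1 at 2.01 and Spic at 1.11 against the F4/80-low gate. The red pulp call also changed without the F4/80-intermediate WX array (adjusted p = 0.0355, higher) and with arrays only centred on their medians (0.0340, higher), where Spic and Vcam1 lost theirs (0.0861 and 0.196). Of 9 small peritoneal macrophage genes 6 were lower (adjusted p = 9.11e-05) and 7 adjusted over the list alone, and of 13 monocyte genes 8 were lower and 1 higher (adjusted p = 0.00190; adjusted p = 0.201 with an estimated correlation) and 9 lower adjusted over the list alone. Against the F4/80-intermediate gate these 2 lists gave adjusted p of 0.240 and 0.578, and Ccr2, at -1.71 ± 0.13 against both gates, was at -0.05. Adgre1 was higher by 1.31 ± 0.19 (adjusted p = 7.27e-05) against both gates, but by 0.50 (adjusted p = 0.106) against the F4/80-intermediate gate and by -0.22 with scaling between arrays. Itgam was at -0.38 ± 0.080 (adjusted p = 0.00218), and at 0.16 (adjusted p = 0.240) against the F4/80-intermediate gate. Of 19 cholesterol and LXR target genes 7 were higher and 7 lower (adjusted p = 0.946), as adjusted over the list alone, with Lpl at 2.62 ± 0.22, Pltp at 2.09 ± 0.17 and Pparg at -1.20 ± 0.11 (5 of 6 splenic arrays), and the list's median change, -0.096, and mean, 0.32, differ in sign.

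Genes of the sex chromosomes also separated these groups. Xist, the X-inactivation transcript of female cells, was not well above background in wt Kupffer cells. It was 27.3-fold lower there in the fit (adjusted p = 1.93e-09), and at least 30.7-fold lower by its Cy5 signal after loess and Aquantile. Eif2s3y, a gene of the Y chromosome, was 1.47 ± 0.19 higher in wt Kupffer cells (adjusted p = 2.67e-05), with signal above background on 2 of 6 splenic arrays. Eif2s3y was chosen after its values were seen. AK041014 was 4.17 ± 0.070 higher in wt Kupffer cells than in the CRIg-negative splenic cells (adjusted p = 4.78e-15).

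**Figure D4:**
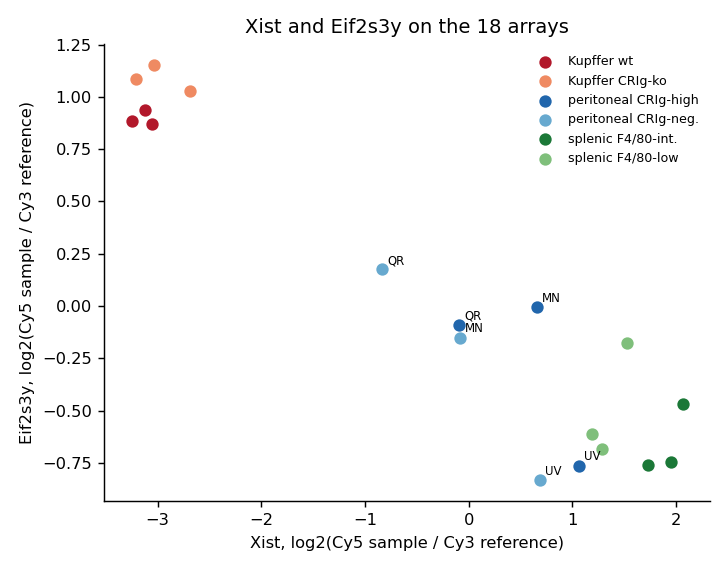
Log2 ratio of sample to reference for Xist (x axis) and Eif2s3y (y axis) on each of the 18 arrays, with a color for each group and the letter pairs beside the peritoneal arrays. Kupffer arrays sit at low Xist and high Eif2s3y, splenic arrays at high Xist and low Eif2s3y, and peritoneal arrays between on the Xist axis, with the UV pair lowest of all in Eif2s3y.

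In all 3257 genes were higher and 2536 lower in Kupffer cells, 30.7% of 18864, and 457 of these differed by at least 2-fold. Of the 5793, 3757 had ranges that did not overlap. Kupffer and splenic arrays shared no day, and with the day as a random block 3896 genes were called, with no list named here losing its call.

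The sixth comparison set the mean of both peritoneal groups against the mean of both splenic gates. Peritoneal cells were higher in large peritoneal macrophage genes and, in calls lost with an estimated correlation, in complement and coagulation genes. Pf4 was 6.86 ± 0.18 higher (116-fold, adjusted p = 7.82e-13), Saa3 6.77 ± 0.14, the matrix protein gene Ecm1 6.36 ± 0.17, Prg4 6.02 ± 0.38, C4b 5.24 ± 0.16, Fn1 5.22 ± 0.19, Serpinb2 5.17 ± 0.19 and Saa1 4.85 ± 0.086. Prg4 and Serpinb2 were above background on 5 of 6 splenic arrays. Prg4 rested on 2, Cfb on 4 and Pf4, Ecm1 and AK041014 on 5 of 6 peritoneal arrays, and Pf4 on 5 of 6 splenic arrays. Of 19 large peritoneal macrophage genes 18 were higher (camera adjusted p = 2.86e-28), as adjusted over the list alone. Of 19 complement genes 12 were higher and 4 lower (adjusted p = 0.000315; adjusted p = 0.0751 with an estimated correlation), as adjusted over the list alone, with Cfb at 2.13 ± 0.11 and Itgax at -3.35 ± 0.086. Of 21 coagulation genes 11 were higher and 3 lower (adjusted p = 0.00111; adjusted p = 0.0751 with an estimated correlation), as adjusted over the list alone, with F10 at 3.35 ± 0.13, the protein S gene Pros1 at 3.09 ± 0.11 and Procr at -1.05 ± 0.12. Of 19 scavenger and efferocytosis receptors 10 were higher and 5 lower (adjusted p = 0.0333; adjusted p = 0.344 with an estimated correlation), as adjusted over the list alone, with Msr1 at 2.75 ± 0.12, Stab1 at 2.47 ± 0.15 and Mrc1 at -2.43 ± 0.099. The scavenger call was lost without the F4/80-intermediate ST array (adjusted p = 0.0557), without both splenic OP arrays (0.0517), with scaling between arrays (0.0948), on the compared arrays alone (0.0601) and against the F4/80-intermediate gate (0.573), where the complement call was lost too (0.111). Mrc1 was at -0.16 (adjusted p = 0.396) against the F4/80-low gate. Adgre1 was 1.41 ± 0.15 and Itgam 1.99 ± 0.065 higher in peritoneal cells.

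Splenic cells were higher in red pulp macrophage, MHC class II and interferon-stimulated genes, all in calls that were lost with an estimated correlation. Vcam1 differed by -5.28 ± 0.15 (38.8-fold), Plbd1 by -4.56 ± 0.11, Spic by -4.36 ± 0.11, Adamdec1 by -4.28 ± 0.14, Itgb5 by -4.15 ± 0.10, Ear2, a ribonuclease gene, by -4.12 ± 0.16, the beta-globin gene Hbb-bt by -4.07 ± 0.48 and Ddit4 by -4.04 ± 0.26 (4 of 6 splenic arrays). The size of some of these falls depended on the gate, with Vcam1 at -8.24 against the F4/80-intermediate and -2.31 against the F4/80-low splenic gate, and Spic at -6.28 and -2.43. Of 12 red pulp genes 8 were lower in peritoneal cells and 2 higher (camera adjusted p = 0.000134; adjusted p = 0.0751 with an estimated correlation), with Slc40a1 at -3.82 ± 0.11, Hmox1 at -2.07 ± 0.13 and Trf at 1.62 ± 0.11. The red pulp call was lost against the F4/80-low gate (adjusted p = 0.787), where Hmox1 was at 0.14 (adjusted p = 0.624), and Trf was at 0.27 (adjusted p = 0.179) against the F4/80-intermediate gate. Of 12 MHC class II genes 8 were lower (adjusted p = 7.65e-07; adjusted p = 0.0751 with an estimated correlation), with H2-Ab1 at -3.00 ± 0.26 and Cd74 at -2.78 ± 0.23, and 9 adjusted over the list alone. Of 13 interferon-stimulated genes 11 were lower (adjusted p = 2.20e-07; adjusted p = 0.0751 with an estimated correlation), with Ifit3 at -2.15 ± 0.11, Cxcl10 at -2.07 ± 0.16 and Isg15 at -1.57 ± 0.12. Of 11 dendritic cell genes 6 were lower (adjusted p = 1.24e-05; adjusted p = 0.0751 with an estimated correlation), with Dpp4 at -1.90 ± 0.14. Counts adjusted over the list alone were the same for the red pulp, interferon-stimulated and dendritic cell lists. Of 17 Kupffer cell genes 6 were higher and 7 lower (adjusted p = 0.366, and 0.0151, lower, against the F4/80-intermediate gate), as adjusted over the list alone, with Fabp7 at 3.63 ± 0.12 and Cd5l at 2.48 ± 0.18 (0.036 against the F4/80-intermediate gate, adjusted p = 0.941).

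Markers of other blood cells moved with the splenic genes. Of 13 erythroid genes 11 were lower in peritoneal cells (camera adjusted p = 1.99e-07; adjusted p = 0.0710 with an estimated correlation), with the alpha-globin gene Hba-a1 at -4.35 ± 0.67 and Alas2 at -2.06 ± 0.19. Of 13 B cell genes 10 were lower and 1 higher (adjusted p = 5.14e-06; adjusted p = 0.0751 with an estimated correlation), with Cd79b at -1.87 ± 0.14 and Ly6d at -1.62 ± 0.13, and 11 lower adjusted over the list alone. Of 20 T and NK cell genes 8 were lower and 1 higher (adjusted p = 0.00673; adjusted p = 0.0751 with an estimated correlation, and 0.0748 with the Cy5 channel alone), with Ccl5 at -1.76 ± 0.18. Of 13 monocyte genes 8 were lower and 2 higher (adjusted p = 0.00134; adjusted p = 0.158 with an estimated correlation), with Nr4a1 at -3.09 ± 0.23, Cd300e at -2.55 ± 0.18 and Hp at 2.26 ± 0.15. Of 21 immediate early and stress genes 4 were lower and 1 higher (adjusted p = 0.0172; adjusted p = 0.588 with an estimated correlation), with Gadd45b at -2.32 ± 0.15. The immediate early call was lost without the F4/80-intermediate OP array (adjusted p = 0.0600), the F4/80-low OP array (0.190) or both (0.544), and with arrays only centred on their medians (0.154). Against the F4/80-intermediate gate the T and NK cell, monocyte and immediate early calls were lost (adjusted p = 0.114, 0.996 and 0.829), and Ccl5 was at -0.50 (adjusted p = 0.122), while Hp was at 0.43 (adjusted p = 0.0964) against the F4/80-low gate. Except for the B cell genes, counts adjusted over the list alone were the same for these lists.

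**Figure D5:**
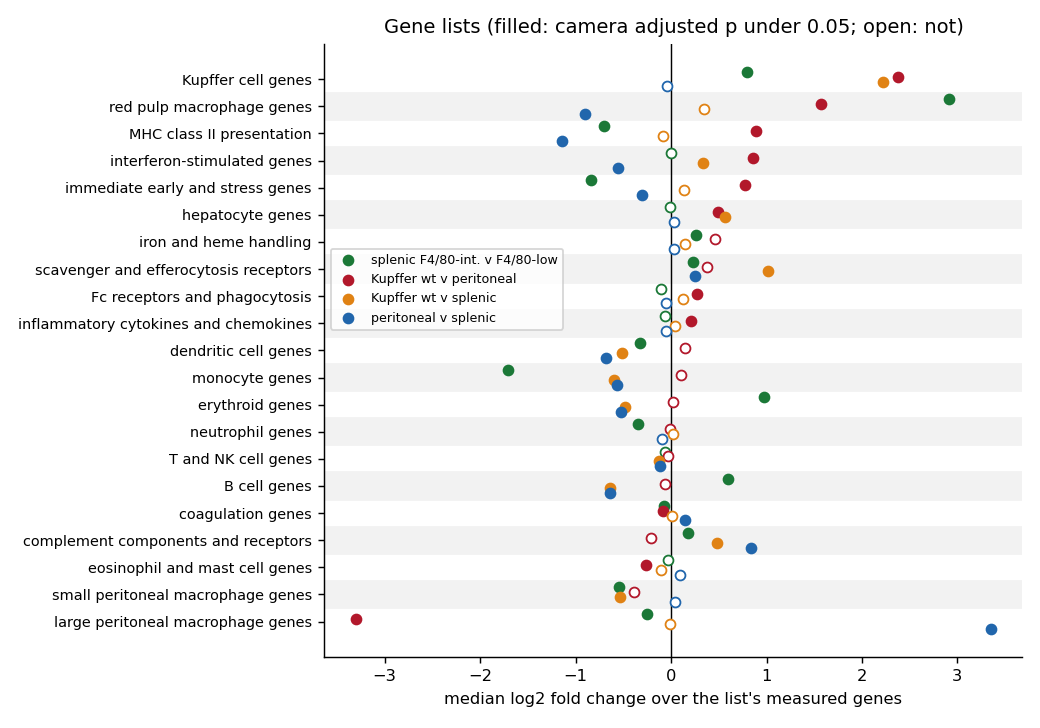
Median log2 fold change over the measured genes of each list (x axis) for 21 lists called in at least 1 of 4 comparisons (y axis), with a color for each comparison and filled points for lists with a camera adjusted p under 0.05. Large peritoneal macrophage genes lie furthest from 0, and Kupffer cell genes are higher in Kupffer cells than in either other tissue.

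In all 2747 genes were higher and 2679 lower in peritoneal cells, 28.8% of 18860, and 699 of these differed by at least 2-fold. Of the 5426, 2463 had ranges that did not overlap. With the day as a block 4839 genes were called and within the shared day 4533, with no list named here losing its call. AK041014 was 2.11 ± 0.060 higher in peritoneal cells (adjusted p = 5.52e-13), but 0.05 (adjusted p = 0.677) with CRIg-negative gates only.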

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

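The fits within 1 day, those without both splenic OP arrays and those of peritoneal cells against a single splenic gate were chosen after the results were seen. All other alternatives were planned. Of the values of named genes under all alternatives, 350 of 459 kept their direction and side of the threshold in the knockout comparison, all but 1 of 216 between the peritoneal gates, 1214 of 1222 between the splenic gates, 1291 of 1294 for Kupffer wt against peritoneal, 1218 of 1228 for Kupffer wt against splenic and 1489 of 1496 for peritoneal against splenic. The others were weaker, apart from 6 that were stronger and 11 that reversed. Of the values of lists, 85 of 110, 71 of 80, 348 of 360, 357 of 390, 345 of 364 and 419 of 448 did so in the same order, and the others were mostly weaker. The estimated correlation ended 34 calls. The cause of a change was not tested except where stated.

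The 24 genes of the knockout became 2 with the scanner's log ratios and with the deposited table (AK041014 and Kcns2, the latter chosen after its values were seen), 40 with an offset of 16, 1 with median centring, 2 with scaling (AK041014 and Gpx3, chosen in the same way, 50% higher), 1 with Cy5 alone, 37 without the filter, 11 with the stricter filter, 1 on the compared arrays alone, 79 with an intensity trend and robust prior, 1 at 2-fold, and 722 with the day as a block and 689 within day 1, each of which rests on ko array 2 alone and says nothing of the other ko arrays. The 1 gene of the peritoneal gates became 4 with array weights (also Emb, Lyve1 and Rxrg, chosen after their values were seen). The 3034 genes of the splenic gates became 1654 with median centring (70.4% higher against 52.6%), 1964 within day 4, 1914 within day 5 and 667 at 2-fold. Day 5 holds only 1 array per splenic gate, with the spread taken from other groups, so its count gives no test of the gates. For Kupffer wt against peritoneal, 6310 became 3933 with median centring and 816 at 2-fold. For Kupffer wt against splenic 5793 became 457 at 2-fold, and for peritoneal against splenic 5426 became 699 at 2-fold. There, median centring gave 4232 genes with 64.2% higher against 50.6%. The lower counts at 2-fold follow from the stricter criterion. Which genes were called between tissues also depended on the processing. In the same order, Cy5 alone kept 64.45%, 57.16% and 71.71% of the calls of the main fit. The scanner's log ratios kept 69.32%, 63.09% and 84.15%, and median centring 52.35%, 57.57% and 64.71%. Scaling kept 68.64%, 67.75% and 91.56%, and the fit with an offset of 16 kept 91.6%, 90.2% and 94.47%. Leaving out 1 array gave 1 to 172 genes for the knockout, 1 to 1 for the peritoneal gates, 2410 to 3354 for the splenic gates, 4758 to 5977, 4270 to 5865 and 4682 to 5436 for the tissues in the order above, and 7262 to 8404 for the F test.

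Reversed values were AK041014 in Kupffer wt against peritoneal at -0.0040 against the CRIg-high gate and -0.049 for the mean of wt and ko cells, which follows from the sort and the genotype. In Kupffer wt against splenic, Adgre1 was at -0.22 with scaling, Itgam at 0.16 and Slc40a1 at -0.21 against the F4/80-intermediate gate, and Spic at 1.11 and Vcam1 at 2.01 against the F4/80-low gate. In peritoneal against splenic, Hmox1 was at 0.14 against the F4/80-low gate. With Cy5 alone, Olfr1261 in the knockout was at 0.55, Ptprn2 at 0.038 and Tmem47 at 0.0037. Among lists, the monocyte genes (adjusted p = 0.578) and red pulp genes (adjusted p = 0.000486) of Kupffer wt against splenic and the monocyte genes of peritoneal against splenic (adjusted p = 0.996) turned against the F4/80-intermediate gate, and the inflammatory genes of the knockout within day 1 (adjusted p = 0.994).

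With the letter pair, the replicate name in the titles, as a block, 3 genes were called between the peritoneal gates and 3284 between the splenic gates, and as a random block 5943, 5420 and 4748 between the tissues and 7910 by the F test. Between the peritoneal gates the block added the calls of Arg1 and BC018464, and between the splenic gates it changed the call of no gene or list named there. As a random block it changed the call of no gene named in the comparisons between tissues and ended 1 list call, that of the Fc receptor genes of Kupffer wt against peritoneal (adjusted p = 0.0561), which the same test did not make without the block either. Kupffer arrays of the same number were not paired (r of -0.029 to 0.035 across genes, with 0 of 6 arrays closest to their own number), and the block gave 5 genes there. The share of spots above background, 74.8% on the dimmest array, limits what dim genes can show.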

Other observations

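The tests of AK041014, for Xist and Eif2s3y that of the sex of the pools, for Kupffer cells those of the batch on 2 lists, and the splits between tissues that keep pairs together were chosen after the results were seen, and the other tests were planned.

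AK041014 separated the CRIg-positive arrays of liver and peritoneum from all CRIg-negative arrays. The lowest CRIg-positive array lay 3.94 log2 units above the highest CRIg-negative array. In limma no other gene (0, and 0 at an unadjusted p under 0.05) reached 2-fold the same way in both the genotype and the peritoneal comparison. Between the peritoneal gates alone 0 other genes reached 2-fold at any p, against 3 for the genotype, so the peritoneal side fixed that count. This argues against a large share of cells of another type in the CRIg-high peritoneal samples. It does not address a small share, or other cells in the liver samples alone. A candidate explanation that stays open is that the probe measures the sorted and deleted gene, since the splenic arrays, sorted as CRIg-negative, lay only 0.040 from the ko arrays. The table of gene names used here does not settle what the probe binds.

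Xist and Eif2s3y moved in opposite directions between Kupffer cells and each other tissue. Between peritoneal and splenic cells Xist differed by -1.39 (adjusted p = 8.62e-05) and Eif2s3y by 0.30 (adjusted p = 0.176). Across both peritoneal gates, the arrays of pair UV differed from those of pair QR by 1.34 in Xist (adjusted p = 0.00218) and by -0.84 in Eif2s3y (adjusted p = 0.0205). Both went the same way in both gates, and 141 genes differed between these pairs. Each pair has 1 array per gate, so the gates stand as replicates here. If a letter pair marks 1 pool, these p-values do not measure the spread between pools. Eif2s3y was above background on neither UV array, so the size of its difference is not exact. Other pairs did not all follow this. In the CRIg-high gate the MN array exceeded the QR array in Xist (0.65 against -0.095) and in Eif2s3y (-0.0057 against -0.092). In the CRIg-negative gate the MN array was higher in Xist (-0.085 against -0.836) and lower in Eif2s3y (-0.151 against 0.175), as between UV and QR. In both splenic gates the OP array exceeded the ST array in Xist (2.07 against 1.73 and 1.53 against 1.28). It did so in Eif2s3y too (-0.47 against -0.76 and -0.18 against -0.68), which was not above background on the ST arrays. A shift of the reference is argued against by the Cy3 signal of Xist, which differed by -0.053 between Kupffer and splenic arrays. Between the UV and QR arrays, other genes of the Y chromosome did not follow Eif2s3y. Among those above background on all 18 arrays, the difference between UV and QR was -0.068 in Kdm5d (adjusted p = 0.924), -0.041 in Zfy1 (0.982; 0.052 in the CRIg-high gate and -0.13 in the CRIg-negative gate) and -0.058 in Uba1y (0.960). Between Kupffer and splenic arrays, where Eif2s3y differed by 1.47, Kdm5d differed by 0.27, Zfy1 by 0.18 and Uba1y by -0.092 (adjusted p = 0.000797, 0.0229 and 0.219), so whether these probes respond to a Y chromosome is not known. Xist was above background on 0 of 3 wt Kupffer and 6 of 6 splenic arrays. Eif2s3y was so on 3 of 3 and 2 of 6. If each probe measures only its named gene, the wt Kupffer pools held male mice and the splenic pools female mice. Different shares of male and female mice in the pools are a candidate explanation that stays open and may then enter every comparison between tissues. A difference between the cells in the regulation of both genes would then need pools of both sexes, and stays open as well. The labels used here give no sex. Whether any other gene named in the text follows the sex of the pools was not tested.

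Kupffer cells differed from both other tissues, and the software extracted their arrays on other days. The Cy3 channel accounted for a median of -3.35% of the ratio change over the 816 genes at 2-fold against peritoneal. Over the 457 against splenic it was -1.52%, with 12 and 10 genes over 50%. This argues against a shift in the reference as the main cause of these larger changes. The smaller changes among the 6310 and 5793 genes called were not tested in this way. The Kupffer cell list was called upward with an estimated correlation against both tissues, with a median change of 2.37 against peritoneal and 2.22 against splenic. This cannot test labelling or isolation of the liver samples in a batch of their own, since sorted Kupffer cells would carry these genes with or without it. For the large peritoneal list, which was fixed beforehand, no such batch was needed for a difference of this size. The list had a median change of -3.30 against peritoneal but -0.010 against splenic. It differed by 3.28 between peritoneal and splenic arrays of a shared day, where no liver array enters. Peritoneal cells would carry these genes with or without a batch. Members such as Prg4 had low mean log2 Cy5 signal in both wt Kupffer (5.967) and splenic cells (6.577), where a batch could hardly show. A batch that adds to the list's difference is thus not excluded. For the other differences such a batch cannot be told apart from tissue, since 0 arrays of another tissue shared a day with wt Kupffer arrays. A difference between the tissues in biology may underlie those as well and was not separated from that batch.

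Other splits of the same arrays were counted for each comparison. For the knockout and both pairs of gates there are only 10 splits of 3 against 3 arrays, too few for a share under 0.05. The knockout called 24 genes and the highest other split 1, and 1 of the 10 splits called as many as the real one. The splenic gates called 3034 and the highest other 1, again with 1 split as high. Among the 4 splenic splits that part all pairs, the highest other called 0, and the other splits put both arrays of a pair on the same side. The peritoneal gates called 1, and 3 splits called as many. The highest other called 46 genes, with both UV arrays and the CRIg-high MN array on 1 side, which points to a structure of the pairs, while among the 4 splits that part all pairs the highest other called 0.

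Between tissues, the arrays on each side of a split were fitted as a single group beside the groups not compared. The real counts therefore differ from those of the main fit, which kept the gates apart. Splits of single arrays never called as many genes as the real one. Kupffer wt against peritoneal called 6495 genes and the highest other of 84 splits 99. Kupffer wt against splenic called 4490 and the highest other of 84 splits 2750, with the F4/80-low arrays as a side of their own, which points to the structure of the splenic gates. Peritoneal against splenic called 4599 and the highest other of 100 drawn splits 1890. In each of the 3, only 1 split, the real one, called as many. Most of these splits part letter pairs, which the real ones keep together. Only 10 splits in each comparison part no pair, too few for a share under 0.05, and the highest other among them called 0, 0 and 11 genes in the order above.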
